A study of Homo sapiens with 4 samples.

How the data were processed

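RNA-seq libraries of 697 cells, 2 treated with 1 µM MZ1 and 2 with DMSO for 24 h, were compared. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made from it with the Illumina TruSeq RNA kit, which in general use selects polyadenylated RNA and does not mark the strand. The deposited values are raw read counts per gene, under Ensembl gene IDs, per the file headers and the whole-number values. HISAT2 2.2.0 and the genome build hg38 are named per the submitters' processing notes. The counting program, its gene annotation and its strand setting are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart and near-identical copies may share or lose reads. The lowest total of any gene over the 4 libraries was 2 counts. Some listed genes have no row, among them CCND2 (D cyclins and markers lowered by BET inhibition), CD37, BIRC3 and BCL2A1. Whether these had almost no reads or their rows were left out is not known, so counts of list members cover tested genes only. Groups were taken from each sample's title and treatment label, and all 4 count columns were used.

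All 28814 IDs were found in GENCODE release 29 (GRCh38, the same build as hg38), from which positions and gene types were taken, and 28597 had a symbol in the gene name table. The others kept the name that GENCODE gives. The exonic length shared with other genes was computed from the same annotation for genes in the lists and genes named by the fixed rule below. Of these, values above 40% for genes named here, or above 10% for genes with the largest changes, are given beside them. For other genes it was not computed.

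Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (16862 genes), libraries were scaled with TMM, and a quasi-likelihood model (glmQLFit, default settings, and glmQLFTest) was fitted to all 4 libraries with treatment as the only term. P-values were adjusted with the Benjamini-Hochberg method over all tested genes and genes with an adjusted p below 0.05 were called. Standard errors of log2 fold changes were derived from the unshrunk coefficient and the F statistic. They understate the error of genes with few reads in a group and are not given for those. Levels are TMM-normalised CPM, as mean ± SD of 2 libraries. For a gene with 0 counts in a group the fold is a lower bound against 3 counts over that group (0.09 CPM for DMSO, 0.107 for MZ1), and for 1 to 3 counts the ratio of summed counts is given with an exact 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The depth of 14246367 to 16488005 counts per library therefore leaves fold changes of genes near the floor open over a wide range.

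Gene lists (30) were written before the data were examined. Lists with at least 3 tested members were tested two-sided with camera in limma 3.58.1 on voom values, with the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 28 lists. Camera with an estimated correlation and fry were run beside it. Genes named in the text followed a rule fixed at the same time: 12 genes always named; the 8 largest rises and 8 largest falls among called protein-coding genes with a mean log2 CPM of at least 3 and groups that do not overlap, leaving out clone, antisense, mitochondrial, immunoglobulin variable and Y-linked symbols; and for each list up to 3 members with the smallest adjusted p in each direction, or all members of a list of 9 or fewer. Genes named outside the rule are said to be so, and a few genes and 1 list that the rule covers are not reported here.

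The analysis was tested on simulated counts with the real libraries' means and sizes for the comparison of MZ1 with DMSO (16215 genes). It recovered 36.2% of genes changed 1.25-fold, 66.0% of those changed 1.5-fold, 78.7% of those changed 2-fold and 93.8% of those changed 4-fold, with 1 false call among 156. A list shifted by 0.3 on the log2 scale was called and 0 of 26 unshifted lists were, by camera with the preset correlation. Few genes were changed in the simulation, against 84.2% of tested genes called in the real data, so its error rates may not carry over. Simulated genes varied independently of each other, so the simulated lists cannot test the preset correlation.

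The replicates were compared first. A chi-square test of their counts gave 2.56 per degree of freedom for DMSO and 2.26 for MZ1, so replicates differed by more than sampling noise and each counts as 1 library. The biological coefficient of variation was 3.8%, and the first principal component, which separated the treatments, held 96.3% of the variance. Alternatives to the scaling, the count filter, the test (DESeq2 1.42.0, limma-voom, another edgeR setting), the set test, the replicate block, the most abundant genes and each library in turn were run. Neighbouring genes and Fisher's exact tests were computed in Python 3.11.15 with SciPy 1.17.1.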

Results

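RNA was sequenced from 697 cells, an established human B-cell precursor leukaemia line, after 24 h with 1 µM MZ1 or with the same volume of its solvent, DMSO. MZ1 joins the bromodomain ligand JQ1 to a ligand of the VHL ubiquitin ligase, so that proteins of the BET family are marked for degradation. There were 2 libraries per group. The count table held 16005427 and 16488005 counted reads for the DMSO libraries and 14544789 and 14246367 for the MZ1 libraries, over 28814 genes. The comparison asks which transcripts of this leukaemia line differ after a day with the degrader. No spike-in is named in the labels, so each level is a share of its library (in CPM, the usual scaling of counts to library size) and each log2 fold change (MZ1 over DMSO) is relative to the other genes. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

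MZ1 changed most of the measured transcriptome. MYC, the transcription factor that drives growth genes, fell from 508 ± 18.9 to 5.82 ± 0.37 CPM (SD, n = 2 per group), or 87.1-fold. Genes of ribosome assembly, DNA replication, the proteasome, glycolysis and the pre-B cell receptor fell as groups in camera's test with its preset correlation, but not with an estimated one (adjusted p = 0.253 to 0.344 with an estimated correlation). Histone, ribosomal protein, mitochondrially encoded and lysosomal genes rose as groups with the preset correlation, and again not with an estimated one (adjusted p = 0.267 to 0.485 with an estimated correlation). The estimated setting rests on 2 residual degrees of freedom and has little power, so its lack of calls does not decide against these lists. Of 16862 genes tested, 7222 were higher and 6969 lower at an adjusted p below 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), and 2671 were not called. At least 2-fold changes made up 4887 of the rises and 4425 of the falls. Among 12639 protein-coding genes 4866 were higher and 6165 lower, whereas among the 4223 genes of all other types 2356 were higher and 804 lower. The groups did not overlap for 15390 genes (91.3%), where chance gives 33.3% for 2 libraries against 2. A permutation of 2 libraries against 2 cannot give a two-sided p below 0.333, so the calls rest on the spread that edgeR pools over genes. With upper-quartile scaling all log2 fold changes shifted up by a median of 0.271, and 8304 genes were higher and 5880 lower, so 58.5% of the calls were rises in place of 50.9%.

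Of 30 gene lists fixed before the data were examined, 28 had enough measured members for camera, a test of a list against all other genes. Of these, 6 were higher and 8 lower at an adjusted p below 0.05 with the preset inter-gene correlation. With a correlation estimated from each list, which rests on 2 residual degrees of freedom, camera called 0 of the 28 (3 had an unadjusted p below 0.05), and fry, which tests a list by itself, called 27. Counts of list members adjusted over the list alone equalled those adjusted over all genes, except for DNA replication as given. For 166 of the 167 genes named by the fixed rule, both MZ1 libraries lay on the same side of both DMSO libraries, and the exception was XIAP. The rule favours such genes, as it requires non-overlapping groups for the largest changes and small adjusted p for members of longer lists. This count is therefore not separate evidence.

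The transcripts of BRD2 and BRD3, of the BET family, did not move together. BRD3 (chromosome 9, 134030305 to 134068535, GRCh38) rose from 93.9 ± 4.3 to 267 ± 4.8 CPM, a log2 fold change of 1.51 ± 0.05 (SE; edgeR adjusted p = 1.37e-19). BRD2 (chromosome 6, 32968660 to 32981505) fell from 350 ± 0.91 to 319 ± 4.1 CPM, a change of −0.13 ± 0.04 that turned to 0.14 with upper-quartile scaling. In the list of BET genes and the VHL ligase complex 3 of 8 members were higher and 5 lower (camera adjusted p = 0.489). RBX1, the RING subunit of the ligase, fell 6.81-fold, CUL2 2.43-fold, ELOB 2.34-fold and ELOC 1.41-fold. VHL was called higher by 0.16 ± 0.06, but it did not pass the test with library totals alone (0.08), without a count filter (0.08), or without DMSO replicate 2 (0.03) or MZ1 replicate 2 (0.13).

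Genes known as markers of BET inhibition formed a raised and a lowered list. Of the markers known to be raised, 8 of 9 were higher and 1 was lower (median log2 fold change 2.91; camera adjusted p = 0.00265; adjusted p = 0.344 with an estimated correlation). HEXIM1, which holds the elongation factor P-TEFb inactive, rose from 44.6 ± 2.4 to 121 ± 7.9 CPM (log2 fold change 1.44 ± 0.06). TXNIP rose 11.5-fold. SERPINI1 rose 7.40-fold, from 0.51 to 3.83 CPM, an imprecise value that rests on 17 DMSO reads. Among the members that rose are the histone genes H2BC21, H2BC12, H2BC11 and H1-2. These also belong to the list of replication-dependent histone genes, so the calls of these lists are not separate evidence. ZMYND8, a chromatin reader, fell 16.4-fold. All 4 measured markers known to be lowered fell: MYC (chromosome 8, 127735434 to 127741434; ENSG00000136997) by 6.45 on the log2 scale, to 163 reads over the MZ1 libraries, the interleukin-7 receptor gene IL7R, BCL2 and CDK6 (median −3.11; camera adjusted p = 0.00339; adjusted p = 0.344 with an estimated correlation). Transcription elongation genes split, with 9 of 21 higher and 9 lower (camera adjusted p = 0.977). AFF4 of the super elongation complex rose 3.66-fold, whereas NELFCD of the pausing factor NELF fell 9.55-fold and NELFA 3.41-fold. The list's median was −0.06 and its mean −0.11, but camera's direction was up and the median was 0.21 with upper-quartile scaling.

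**Figure D1:**
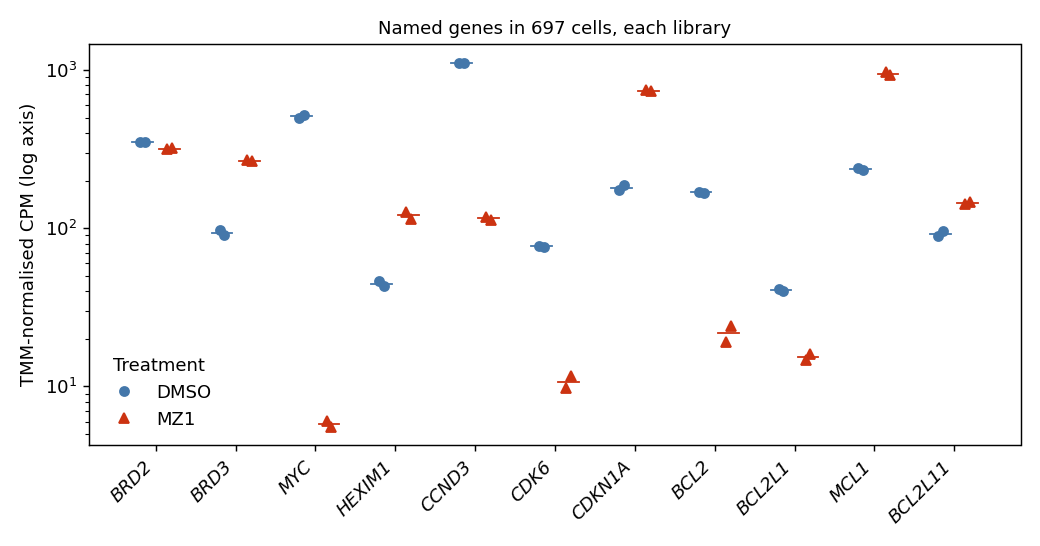
Level of 11 genes named in advance, in TMM-normalised CPM on a log axis. Each circle is a DMSO library and each triangle an MZ1 library, with a short line at each group's mean (n = 2). MYC lay at 508 CPM with DMSO and 5.82 with MZ1, the widest gap of the 11, and BRD2 the narrowest, at 350 and 319, a difference that turned its sign with upper-quartile scaling.

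MYC targets and genes of nucleolar ribosome assembly fell in 52 of 53 cases (median −2.24; camera adjusted p = 6.67e-16; adjusted p = 0.253 with an estimated correlation). SRM, which makes spermidine, fell from 258 ± 0.27 to 8.58 ± 0.43 CPM, or 30.0-fold. LDHA fell 6.77-fold and the mitochondrial chaperonin HSPD1 6.13-fold. NOP2 was the only member called higher, from 2.40 to 7.55 CPM, and 54.4% of its exonic length is shared with an overlapping gene, so its count is uncertain.

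DNA replication and G1/S genes fell in 35 of 38 cases, with 0 higher, and in 36 when adjusted over the list alone (median −1.79; camera adjusted p = 2.03e-11; adjusted p = 0.344 with an estimated correlation). MCM3 and MCM6, subunits of the replicative helicase, fell 6.97-fold and 6.95-fold, and UHRF1, which maintains DNA methylation, fell 4.198-fold. With upper-quartile scaling 2 of the 38 were called higher. Mitosis and G2/M genes went the other way, with 25 of 34 higher and 7 lower (median 0.36; camera adjusted p = 0.0117; adjusted p = 0.37 with an estimated correlation). ECT2, needed for cytokinesis, rose 3.12-fold, the spindle checkpoint kinase BUB1 2.56-fold and CDC25B 2.19-fold, while FOXM1, a transcription factor of mitotic genes, fell 3.16-fold and BUB3 1.99-fold. Among D cyclins, their kinases and CDK inhibitors 5 of 13 were higher and 6 lower (camera adjusted p = 0.718; median −0.01, mean 0.02, median 0.26 with upper-quartile scaling). The D cyclin gene CCND3 fell from 1113 ± 1.0 to 116 ± 3.2 CPM (log2 fold change −3.27 ± 0.04; edgeR adjusted p = 2.78e-27). CDK6 fell 7.17-fold, from 76.7 ± 0.23 to 10.7 ± 1.2 CPM. CDK4 fell 4.73-fold, with 43.2% of its exonic length shared with TSPAN31. The inhibitors CDKN1A (p21) and CDKN1B (p27) rose 4.09-fold and 3.21-fold. CCND1 rose from 2 reads to 3.83 CPM, a ratio of 63.7 (95% counting interval 17.2 to 533).

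Genes of cell death and survival changed in both directions. BCL2, which blocks mitochondrial apoptosis, fell from 168 ± 3.2 to 21.7 ± 3.6 CPM (log2 fold change −2.96 ± 0.07; edgeR adjusted p = 4.43e-22). MCL1, of the same function, rose from 238 ± 5.0 to 949 ± 27 CPM (log2 fold change 1.997 ± 0.041; edgeR adjusted p = 1.4e-23). BCL2L1 fell 2.65-fold, with 43.0% of its exonic length shared with the antisense gene ABALON. BCL2L11, which encodes the death protein BIM, rose 1.55-fold (0.63 ± 0.05). In the survival list 3 of 8 members were higher and 4 lower (median −0.39; camera adjusted p = 0.953, with the direction reversed when either DMSO library was left out, at adjusted p = 0.552 and 0.592). BIRC2 rose 2.86-fold and BIRC5 1.61-fold, BCL2L2 fell 1.996-fold and CFLAR 1.66-fold, and XIAP was at 55.3 ± 1.2 and 53.7 ± 3.0 CPM (edgeR adjusted p = 0.566, but called higher by 0.23 with upper-quartile scaling, adjusted p = 0.00324). In the death list 9 of 18 were higher and 8 lower (camera adjusted p = 0.644). BMF rose 20.8-fold, BBC3 (PUMA) 4.05-fold and APAF1 3.90-fold, whereas BID fell 5.12-fold, CASP6 3.37-fold and BAX 2.21-fold. Of 23 p53 targets 14 were higher and 8 lower (camera adjusted p = 0.0676). TP53INP1 rose from 24.2 ± 0.81 to 1331 ± 14 CPM, or 54.9-fold, and BTG2 24.96-fold, while PHLDA3 fell 2.60-fold and AEN 1.71-fold. This list passed camera's test with the preset correlation when either DMSO library was left out, a fit with 1 DMSO library. With an estimated correlation over all libraries its camera adjusted p was 0.344. In the same libraries the share of counts from mitochondrially encoded genes was 5.65 ± 0.24% with DMSO and 9.12 ± 0.20% with MZ1.

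Pre-B receptor and surface genes fell in 20 of 25 cases, with 4 higher (median −1.55; camera adjusted p = 2.33e-04; adjusted p = 0.342 with an estimated correlation). IGLL1, part of the surrogate light chain, fell from 492 ± 11 to 7.44 ± 0.09 CPM, or 66.1-fold (edgeR adjusted p = 1.15e-28). DNTT, the polymerase that adds bases at V(D)J joints, fell 13.8-fold and IL7R 9.64-fold. IGHM, the µ heavy chain gene, rose from 1227 ± 2.8 to 7598 ± 109 CPM, or 6.19-fold, CXCR4 rose 2.38-fold and CD9 2.07-fold. Of 23 B-lineage transcription factors 15 were lower and 7 higher (camera adjusted p = 0.12). IKZF1 (Ikaros) fell 14.8-fold, MEF2C 6.04-fold and RUNX1 3.73-fold. IRF4, which acts in light chain rearrangement and plasma cells, rose from 72.9 ± 2.4 to 989 ± 26 CPM, SOX4 rose 2.96-fold and FOXO1 2.41-fold. Of 8 plasma cell genes 3 were higher and 5 lower (camera adjusted p = 0.757). The antibody joining chain gene JCHAIN fell 51.0-fold, MZB1 22.5-fold and FKBP11 5.12-fold, and XBP1 rose 1.35-fold. SDC1 had 0 DMSO counts and 4.84 ± 2.3 CPM with MZ1, at least 54.0-fold higher than a floor of 3 counts over the group. PRDM1 was called lower from 2.04 to 1.04 CPM and SSR4 from 91.7 to 82.4 CPM. Both calls were lost without MZ1 replicate 2 (log2 fold changes −0.85 and −0.08), the PRDM1 call also without DMSO replicate 2 (−0.76). Neither gene was called by DESeq2 (adjusted p = 0.154 and 0.189) or with upper-quartile scaling (−0.70 for PRDM1 and 0.12 for SSR4), nor SSR4 with the stricter count filter (adjusted p = 0.0559).

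Immune signalling lists were mixed. Of 27 interferon-stimulated genes 10 were higher and 16 lower (median −1.67; camera adjusted p = 0.293). STAT2 rose 9.75-fold, IRF7 6.33-fold and IFI6 2.95-fold, and OAS2 fell 12.9-fold and IFIT5 8.70-fold. Of 19 antigen presentation genes 5 were higher and 12 lower (camera adjusted p = 0.0676, but 0.0472 with library totals alone, and 0.0209 and 0.0212 without DMSO replicate 1 or 2). CIITA, which switches on class II genes, fell 5.11-fold, HLA-DPA1 4.66-fold and PSMB8 3.64-fold, whereas HLA-E rose 2.42-fold and B2M 1.46-fold. Of 12 NF-kB targets 5 were higher and 6 lower (camera adjusted p = 0.85); NFKB1 fell 3.99-fold and NFKB2 rose 1.83-fold.

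Metabolic and protein turnover genes also moved in groups. Proteasome genes fell in 28 of 31 cases, with 0 higher (median −0.998; camera adjusted p = 3.51e-08; adjusted p = 0.267 with an estimated correlation), and 2 of the 31 were called higher with upper-quartile scaling. PSMB6 fell 5.06-fold, PSMC3 5.003-fold and PSMD8 3.57-fold. Glycolysis genes fell in 14 of 20 cases and rose in 4 (median −1.35; camera adjusted p = 0.00141; adjusted p = 0.342 with an estimated correlation). ENO1 fell from 1940 ± 27 to 332 ± 2.7 CPM, or 5.84-fold, LDHA 6.77-fold and GPI 4.53-fold, while SLC2A3 rose 3.27-fold and PFKL 2.02-fold. ALDOA was also called higher, with 53.5% of its exonic length in overlapping genes. Of 25 ATF4 and unfolded protein response genes 15 were lower and 7 higher (median −0.71; camera adjusted p = 0.0197; adjusted p = 0.344 with an estimated correlation). The fallers included the amino acid transporter gene SLC7A5 (9.25-fold) and the serine synthesis genes PHGDH (8.32-fold) and PSAT1 (6.33-fold), and the stress transcription factor gene ATF3 rose 5.75-fold. Cholesterol synthesis genes were lower in 14 of 20 cases and higher in 4 (median −0.51; camera adjusted p = 0.0378; adjusted p = 0.37 with an estimated correlation). DHCR7 fell 9.54-fold and SQLE 2.24-fold, and INSIG1, which holds back the pathway's regulators, rose 1.38-fold. This call was lost without DMSO replicate 2 (adjusted p = 0.0615) and with a stricter count filter (adjusted p = 0.0611). Lysosome and autophagy genes rose in 16 of 25 cases and fell in 8 (median 0.80; camera adjusted p = 0.00949; adjusted p = 0.344 with an estimated correlation). MAP1LC3B (LC3B) rose 8.42-fold, the cargo receptor gene SQSTM1 5.46-fold and CTSB 4.82-fold, while TFEB, a transcription factor of lysosomal genes, fell 2.98-fold.

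**Figure D2:**
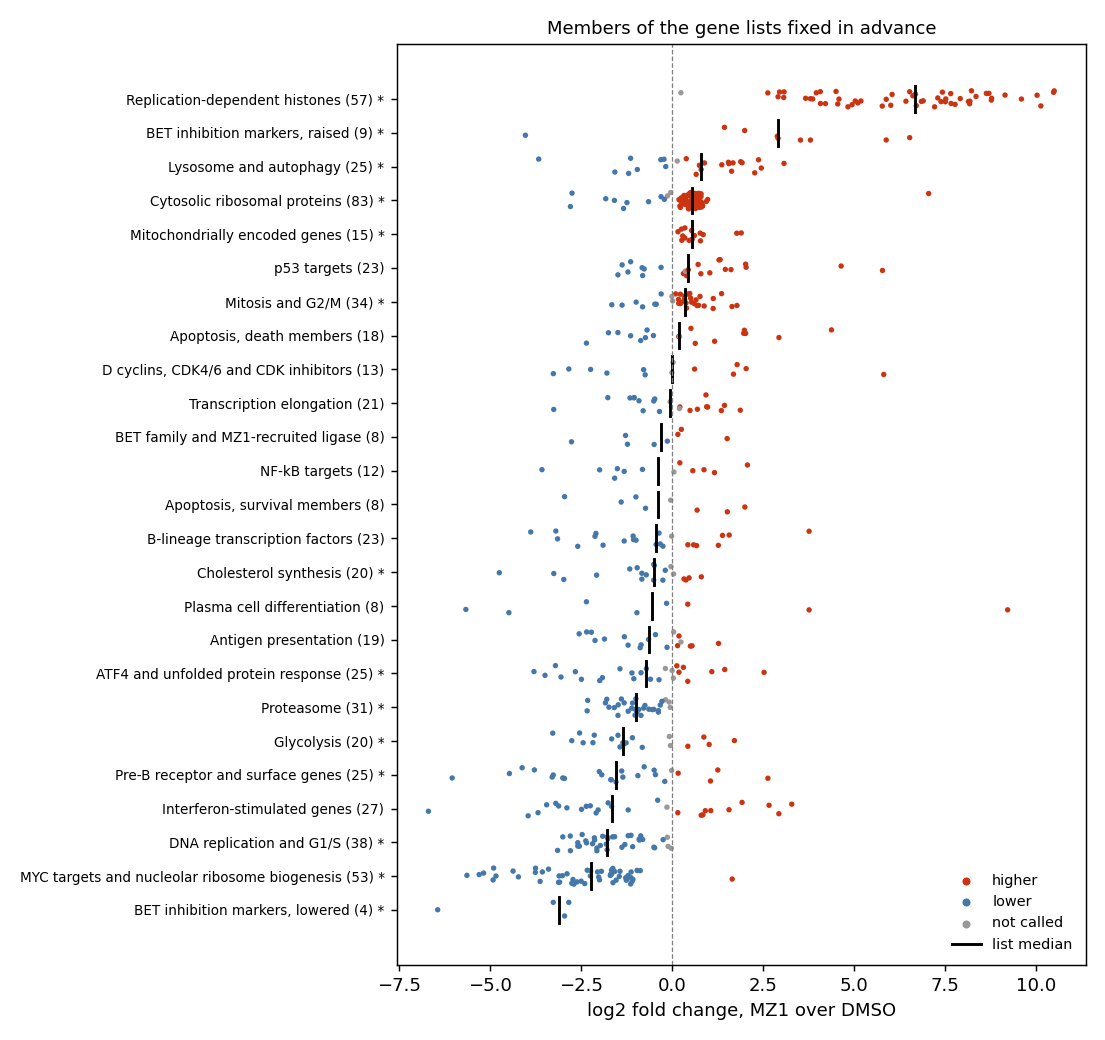
Log2 fold change (MZ1 over DMSO) of each tested member of the gene lists fixed in advance, with 1 row per list and the number of tested members in brackets. Red points were called higher, blue points lower and grey points neither, a black bar marks the list median, and * marks camera adjusted p below 0.05 with the preset correlation. Medians ran from −3.11 for the markers lowered by BET inhibition to 6.69 for the histone genes; the lists of other cell types and 1 list not reported here are not drawn.

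Replication-dependent histone genes rose in 56 of 57 cases, with 0 lower (median 6.69, or 6.53 with the 5 members at 0 counts in a group placed at the floor; camera adjusted p = 3.5e-14; adjusted p = 0.267 with an estimated correlation). H3C6 rose from 4.17 ± 0.53 to 848 ± 33 CPM, H4C8 from 2.74 ± 0.70 to 662 ± 34 CPM and H2AC11 from 4.63 ± 0.45 to 534 ± 1.1 CPM. Their share of all counts was 0.013% with DMSO and 0.858 ± 0.020% with MZ1. Histone copies are near-identical, so single members are uncertain, and most of their mRNA carries no poly(A) tail. Cytosolic ribosomal protein genes rose in 72 of 83 cases and fell in 9 (median 0.55; camera adjusted p = 2.45e-12; adjusted p = 0.344 with an estimated correlation). RPL28 rose 1.97-fold and RPS3 1.75-fold, and the genes with the smallest adjusted p among those that fell were RPL7L1 (2.53-fold), RPL22L1 (6.74-fold) and RPL39L (6.95-fold), paralogs of ribosomal proteins. All 15 mitochondrially encoded genes were higher (median 0.53; camera adjusted p = 1.52e-05; adjusted p = 0.485 with an estimated correlation), or 14 of 15 with library totals alone. The ribosomal RNA MT-RNR2 rose from 5329 ± 290 to 18227 ± 388 CPM and MT-CYB 1.80-fold.

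The largest rises among genes with a mean log2 CPM of at least 3 were in genes close to 0 with DMSO. FCGR1A (chromosome 1, 149782671 to 149792518), an Fc receptor gene, had 0 DMSO counts and 98.7 ± 3.2 CPM with MZ1, at least 1097-fold higher than the floor. It has near-identical copies and shares 24.6% of its exonic length with the histone gene H2BC18 and another gene, so its count is uncertain. PTGER3, MGAM2 and LGR5 also had 0 DMSO counts and were at least 277.9-fold, 253.7-fold and 214.0-fold higher. The thyroglobulin gene TG had 3 DMSO counts and 142 ± 4.2 CPM with MZ1, a ratio of 1579 (95% counting interval 540.0 to 7662), and HFE 1 DMSO count, a ratio of 1153 (206 to 45590). HFE lies between the histone genes H1-2 and H1-3 on chromosome 6, although it shares no exonic length with other genes. The source of its reads was not tested. The linker histone gene H1-3, with 7 and 2 counts in the DMSO libraries, rose by 10.13 on the log2 scale. PLEKHA6, with 5 and 2, rose by 10.11. At so few reads both values are imprecise. The largest falls were ZNF532 (156-fold), SLC16A14 (131-fold), the potassium channel gene KCNJ16 (115.5-fold), CCDC86 (111-fold), RASL10B (105-fold), PYCR1 (101-fold), which makes proline, and GTF3C6 (97.4-fold), a subunit of the RNA polymerase III factor TFIIIC. The folds of these genes rest on few MZ1 reads and are imprecise. ZNF532 and SLC16A14 each had 1 and 4 counts in the MZ1 libraries, KCNJ16 4 and 17, and GTF3C6 3 and 8. The phosphatase gene DUSP9 fell to 3 reads, a ratio of 156 (95% counting interval 53.3 to 761). PYCR1 shares 29.7% and CCDC86 17.2% of the exonic length with overlapping genes.

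The tested markers of other cell types fixed in advance lay at or below 13.8 CPM in both groups. Of 10 myeloid markers 5 were measured, 4 higher and 1 lower (median log2 fold change 3.82; camera adjusted p = 0.231). MPO had 0 DMSO counts and 8.46 CPM with MZ1, at least 94.1-fold higher than the floor. The source of its reads was not tested, so induction of MPO cannot be told from transcription that runs on from a neighbouring gene. ITGAM rose from 0.15 to 7.44 CPM, CD14 from 0.51 to 7.15 and LYZ from 0.18 to 2.65, and CSF1R fell from 5.14 to 0.93 CPM. FCGR1A, also known from myeloid cells but outside the list, was at 98.7 CPM with MZ1, with the doubt given above. Of 10 T cell markers 3 were measured (camera adjusted p = 0.757): CD8A rose from 0.57 to 3.97 CPM, CD8B from 0 counts to 0.89 CPM, and TRAC went from 6.93 CPM to 0 counts, at least 64.7-fold lower. One erythroid marker, ALAS2, rose from 0.30 to 2.50 CPM. Of the epithelial and stromal markers FN1 fell from 8.06 to 0.72 CPM, and COL1A1 was at 11.6 ± 1.3 and 13.8 ± 0.21 CPM (edgeR adjusted p = 0.0872, called higher with upper-quartile scaling). The last 2 lists held too few measured genes for camera.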

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

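The alternatives were chosen before the data were examined. Over the other scalings, filters, tests and the replicate block, 6592 to 8304 of the tested genes were higher and 5880 to 7258 lower, within 1.5 times the reported counts; upper-quartile scaling gave the most rises and the fewest falls and turned the sign of 56 called genes. Requiring at least a 2-fold change left 4887 higher and 4425 lower genes, fewer by construction. Leaving out each library in turn gave 6888 to 7175 higher and 6785 to 6820 lower genes and 14 to 16 lists; the arm left with 1 library is then assumed to vary like the other. The replicate numbers in the labels are not said to pair the libraries, and deviations of same-numbered libraries correlated at 0.014 across genes, so the block was only an alternative: with it 7107 genes were higher, 6856 lower and 14 lists passed, 230 gene calls were lost, and no call of a named gene or list changed. Of the 28 lists 14 passed with camera's preset correlation (15 with library totals alone, 13 with the stricter filter), 0 with an estimated correlation (adjusted p from 0.253; 3 with an unadjusted p below 0.05), and 27 with fry, which does not compare a list with other genes. The estimate rests on 2 residual degrees of freedom. Estimated correlations also differed from the preset 0.01, at 0.82 for mitochondrially encoded genes and −0.008 for MYC targets. Estimates also lay below 0.01 for glycolysis (−0.025), proteasome (0.009) and pre-B receptor genes (0.009). For these lists and MYC targets the values argue against a higher correlation as what removed the calls. With so few residual degrees of freedom this setting has little power, so its lack of calls decides little. For lists with higher estimates, what removed the calls was not tested. Upper-quartile scaling reversed BRD2 to 0.138, XIAP to 0.23 and SSR4 to 0.117, as its median shift of 0.271 exceeds their changes, and XIAP, not called, ran from −0.103 to 0.014 with single libraries left out (positive without MZ1 replicate 2). List directions reversed with fry for survival genes (adjusted p = 0.00649) and plasma cell genes (0.0159). They also reversed for 3 uncalled lists with single libraries left out: survival genes without either DMSO library (camera adjusted p 0.552 to 0.906 over the left-out libraries), elongation genes without either MZ1 library (0.661 to 0.998) and NF-kB targets without MZ1 replicate 1 (0.642 to 0.998). The cause was not tested. Of the named genes' other values under all alternatives 2315 kept direction and call, 11 lost the call (VHL, PRDM1 and SSR4) and COL1A1 gained it, as did XIAP among the reversals above (adjusted p = 0.00324 with upper-quartile scaling). Depth limits genes with 3 or fewer counts in a group, whose folds are bounds or wide intervals, and also genes with few counts such as ZNF532 and H1-3.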

Other observations

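The histone tests and their predictions, the set of abundant genes that follows, and a repeat of the neighbour test were chosen after the values were seen; the other neighbour tests had their predictions written first.

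Among abundant protein-coding genes in no fixed list and not named by the fixed rule (mean log2 CPM of at least 6.5), the 8 largest falls began with SLC7A1, which imports arginine and lysine, at 231 ± 11 CPM with DMSO and 7.16 ± 0.72 with MZ1 (32.3-fold). They went on with UGT3A2 (29.2-fold), the folate enzyme gene MTHFD1 (20.1-fold), the gap junction gene GJA1 (19.6-fold), BCAT1, which acts on branched-chain amino acids (19.2-fold), TRHDE (17.8-fold), the valyl-tRNA synthetase gene VARS1 (16.7-fold) and the purine synthesis gene PFAS (14.6-fold). Without PLEKHA6, which the rule names, the 8 largest rises were ADAMTSL4, from 1.20 ± 0.23 to 221 ± 19 CPM (183-fold), CREBRF (55.5-fold), TSPOAP1, from 22.9 ± 0.97 to 784 ± 3.2 CPM (34.3-fold), SESN3, an inhibitor of mTORC1 signalling (24.7-fold), the AP-1 gene JUN (22.4-fold), KLHL24 (15.8-fold), MXD4, which binds the MYC partner MAX (13.8-fold), and the clock gene CRY2 (10.3-fold). Outside this ranking, IGLL5, at the lambda light chain locus, rose from 54.5 ± 1.9 to 228 ± 7.8 CPM, and its count may hold reads of light chain genes. All of these passed edgeR's test, which the ranking required, and the groups did not overlap. The exonic overlap of these abundant genes with other genes was not computed, so their counts may include reads of other genes. ADAMTSL4 (chromosome 1, 150549369 to 150560937) lies past the 3' end of MCL1 (150574551 to 150579738), which is on the other strand and also rose. Whether reads counted for ADAMTSL4 run on from MCL1 was not tested.

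Among tested genes of types other than protein-coding, 2356 were higher and 804 lower, but not every type followed: 474 of 830 tested lincRNA genes were higher and 181 lower, 624 of 1169 antisense genes were higher and 207 lower, and 31 of 35 small nuclear RNA genes were higher and 1 lower, whereas 13 of 44 small nucleolar RNA genes were higher and 17 lower. Without strand, reads of antisense genes cannot be told from those of the genes they overlap. The share of counts outside protein-coding genes was 2.64 ± 0.01% with DMSO and 4.93 ± 0.01% with MZ1.

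Of 6994 protein-coding genes with at most 5 DMSO reads, 356 (5.1%) had at least 1 CPM in both MZ1 libraries, including markers of unrelated tissues such as TG. MZ1 reads over the exons of all 6994 genes were uneven, the top 5% of genes holding 3.95 times the share expected from exonic length (76.5% against 19.4%). This argues against an even background of genomic or stray reads as the source of all of them. Genes with many reads weigh most in this share, so it cannot exclude a background under part of the 356. Transcription that runs on from an active gene upstream is a candidate explanation for part of the 356. Genes with an active gene ending within 20 kb upstream on the same strand gained reads in 69 of 359 cases (19.2%). Those with an active gene starting within 20 kb downstream did so in 32 of 383 (8.4%) and those with neither in 192 of 5488 (3.5%). The odds ratio was 2.61 for upstream against downstream (95% interval 1.67 to 4.08, Fisher's exact test, two-sided p = 1.6e-05). The repeat without histone genes and with activity taken from DMSO alone gave an odds ratio of 2.6 (Fisher's exact p = 0.000132); TG lies 18.2 kb past PHF20L1 and PTGER3 15.5 kb past ZRANB2. Whether it accounts for the whole set stays open. Of the 356, 71.9% had an active gene on either strand pointing at or overlapping them within 50 kb, against 32.8% of all near-silent genes. LGR5 and MGAM2 lie 1084.8 and 323.8 kb past the nearest active gene upstream on the same strand. Of the other largest rises, FCGR1A lies 226.3 kb past NBPF19 and HFE 96.1 kb past TRIM38. PLEKHA6 lies 25.7 kb past PPP1R15B and H1-3 34.5 kb past H3C8, but with 7 and 9 DMSO counts these are outside the 6994 genes. These distances leave out overlapping genes and genes on the other strand. Induction of the genes by MZ1 was not tested.

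The rise of replication-dependent histone genes is the other pattern weighed. More cells in S phase as the whole cause is argued against by the size of the rise: the histone share with DMSO was 1.5% of that with MZ1, so S-phase cells would have to have been at most that share of the DMSO culture at a constant level per cell. The replication and G1/S list, predicted to rise under this explanation, had a median that fell by 1.789. MYC also fell, so this list may not track the share of cells in S phase and decides little by itself. Reads shared among near-identical copies are argued against by the 6 H1 genes, whose coding sequences differ and whose median log2 fold change was 8.742 (7.04 with 2 of them placed at the floor). More carry-over of RNA without a poly(A) tail cannot be told apart, because 45 of the 46 other tailless RNAs tested lay below 10 CPM, and the rule that such low genes decide nothing was set after the result was seen. Their median was −0.418, with 15 higher and 18 lower, and the abundant RN7SL2 fell from 307 to 141 CPM. Most of this set were small nucleolar RNAs. The U3 RNAs SNORD3A and SNORD3B-1 rose from 0.06 to 2.39 and 2.64 CPM, and SNORD3C from 0 to 1.18 CPM. The small nuclear RNAs RNU4-2 and RNU5A-1 rose from 0 to 1.03 and from 0.03 to 2.15 CPM. Of all 35 tested small nuclear RNA genes, 31 were higher and 1 lower. Only RNU4-2 and RNU5A-1 of these were in the set of 46, and the source of the others' reads was not examined. Their count therefore decides little, and carry-over stays open. Polyadenylated histone transcripts remain a further open explanation, untested here.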
